A study of Mus musculus with 8 samples.

How the data were processed

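The samples were mouse pancreatic ductal adenocarcinoma cells of C57BL/6 background, Setd2 knockout (KO) or wild type (WT), profiled by CUT&Tag with antibodies against H3K36me3, H3K27ac and H3K27me3. The titles gave 8 groups with 1 library each: H3K36me3 over gene bodies, H3K27ac at promoters in 2 settings (1 marked vitro) and H3K27me3 at promoters, each in KO and WT.

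The values come from 1 table that the authors deposited, with 25450 rows named by gene and 8 columns of signal, which is mean coverage per base in each promoter or gene body on a scale set by the authors. The scaling factor, the width of the promoter window and the counting step are not given in the sources used here. Per the submitters' processing notes, the tools were Bowtie2 2.4.2, HOMER and MACS2 2.2.7.1 with the mouse build mm10; their order, settings, filters for duplicates and the HOMER version are not given in the sources used here. The promoter values were checked and came out as whole hundredths when multiplied by 6000 in at least 99.96% of values of each library, so a window of 6000 bases or a divisor of it is implied. The step that best matched low promoter values times 6000 was 0.657 to 0.689, which differed by 4.90% over the 6 promoter libraries. It was sought in a preset range, so smaller steps are not excluded. The deposited values carry no fragment counts, so the depth of each library is unknown and no interval from counting could be given. Values are printed as signal per kilobase, the deposited mean times 1000. Rn45s, the multi-copy ribosomal RNA locus, was the maximum of every library, and reads from repeated or overlapping loci cannot be told apart in these values.

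Rows of 1 gene were joined by the highest mean, which left 25236 genes after 214 rows were joined. Of the rows, 25222 carried a current gene symbol, 118 an older one and 110 matched none of the reference names used. Coordinates came with 18185 rows; the other 7265 were analysed without them. Of the rows with coordinates and a RefSeq locus (assembly GRCm38.p6) of that symbol, 99.9% overlapped it. Genes listed at 0 numbered 7126 (28.2%) and 8294 (32.9%) in the KO and WT H3K36me3 libraries, 1230 and 325 in H3K27ac without the vitro label, 366 and 296 in the vitro pair, and 972 and 1344 in H3K27me3.

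For each pair, the floor was the 25th percentile of the positive values. The floor was added as a pseudocount to both libraries, so log2 ratios are log2((KO + floor) / (WT + floor)), which understates the difference at low genes, and genes entered if their mean over the pair reached the floor. The floors were 2.65 per kilobase for H3K36me3, 3.29 and 2.18 for H3K27ac without and with the vitro label, and 1.54 for H3K27me3. With 1 library per group no test was run: genes were counted at a 2-fold difference, list members at 1.5-fold. A gene list was said to stand apart if its median lay below the 2.5th or above the 97.5th percentile of 10000 random lists of the same size matched on mean signal in 20 bins, with at least 5 members measured. This describes these libraries only. The 28 lists, the comparisons, the thresholds and the named-genes rule were set before the data were examined; the report names lists that stood apart, and the plot of list medians shows others. Some planned gene and list results are not reported here.

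Named genes were Setd2, Bmp2, Cxcl1 and Csf2, the 8 highest and 8 lowest ratios per comparison among genes above the median of mean signal with a symbol that is not a predicted gene, clone, pseudogene or small RNA, up to 3 members of each list described with at least a 1.5-fold difference, the 8 highest and 8 lowest in both H3K27ac pairs, and 5 per direction between the settings. A gene listed at 0 in a library has its values given and no fold. Genes named outside this rule are marked as such.

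The same code was tested on simulated data made from each pair with 200 of 25236 genes changed 4-fold and a noise SD of 0.3 in log2. It recovered 96.0% of raised and 74.0% of lowered genes for H3K36me3, 98.0% and 86.0% for H3K27ac without the vitro label, 99.0% and 95.0% in the vitro pair, and 97.0% and 89.0% for H3K27me3. The observed log2 ratios had SDs of 1.58, 0.67, 0.57 and 0.80 in the same order. No simulated gene was at 0 in only 1 library, as many were in H3K36me3. These rates thus check the code at that noise and do not describe recovery in the real libraries. A planted list changed 1.5-fold reached percentile 100 in each pair, and of 100 random lists 7, 4, 2 and 8 stood apart. The percentile cut itself sets about 1 in 20 for lists of randomly drawn genes. Lists whose members share or neighbour windows, such as Hox genes, could stand apart by chance more often, which was not measured. The same holds for lists of short genes in H3K36me3, because random lists were not matched on gene span.

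Alternatives were a pseudocount 5 times smaller or larger, no filter on low values, a floor at the median of positive values, ratios centred on their median, quantile normalization of the 2 libraries, and the mean over a gene's rows. After seeing the data, removal of the trend of the ratio with level (running median over 50 bins) and, for H3K36me3, a restriction to genes of at least 20 kb were added, as was a check of the acinar list against random draws from the 200 genes nearest to each member in KO over WT ratio and mean signal. The 5 groups of genes by promoter H3K27ac came from the mean of the 2 libraries of the setting not being compared, so that no pair was grouped by its own values; for H3K36me3 the vitro pair was used. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.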

Results

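CUT&Tag, in which an antibody brings a transposase to a histone mark so that the DNA around it is cut and sequenced, was applied to mouse pancreatic ductal adenocarcinoma cell lines with and without Setd2, the enzyme that adds the third methyl group to lysine 36 of histone H3. The 3 marks were H3K36me3 over gene bodies, H3K27ac at promoters (a mark of active promoters) and H3K27me3 at promoters (the mark of Polycomb repression). H3K27ac was measured in 2 pairs of libraries, of which 1 pair carries the word vitro in its labels. The labels describe the cells as cultured tumour cells while the series title speaks of cells sorted from orthotopic tumours, so the pair without the vitro label is named here by that absence only. Each of the 8 combinations of mark, setting and genotype had 1 library, so no difference between knockout (KO) and wild type (WT) has a replicate check. The number of reads behind each library is unknown. The median signal per kilobase over 25236 genes was 8.33 in KO and 7.54 in WT for H3K27ac without the vitro label. It was 6.69 and 6.90 in the vitro pair, 3.85 and 3.23 for H3K27me3, and 3.01 and 2.73 for H3K36me3. The mean H3K36me3 signal ran the other way, 5.20 in KO and 5.80 in WT.

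The Setd2 locus itself (chromosome 9, 110532597 to 110618633, mm10, plus strand) gave an H3K36me3 gene-body signal per kilobase of 2.32 in KO and 2.38 in WT, under the floor set for that mark. Promoter H3K27ac at Setd2 was 25.1 in KO and 15.6 in WT without the vitro label, and 18.8 and 19.4 in the vitro pair. Promoter H3K27me3 was 6.05 in KO and 2.41 in WT. Each value covers a whole promoter window or gene body and measures chromatin, not the transcript or the deleted part, so it checks neither the deletion nor the loss of the enzyme.

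The H3K36me3 comparison asks whether the mark that Setd2 writes differed over gene bodies between the genotypes. Signal was about as often higher as lower in KO: the median log2 ratio of KO over WT was -0.08 over 15488 genes, with 3102 genes at least 2-fold higher and 3174 at least 2-fold lower. All 16 named genes at the ends of the ranking were listed at 0 in 1 of the libraries. Prm3 (a protamine-cluster gene) had a signal per kilobase of 193 in KO, Bola2 146, Tmsb10 (thymosin beta 10, an actin-binding peptide) 145 and Cdkn2d (a cell-cycle inhibitor) 125, and each was listed at 0 in WT. In the other direction, Olfr1344 had 246 in WT, the histone genes H2al1o and H4c14 224 and 145, and Imp3 (a factor of ribosome biogenesis) 142, with each listed at 0 in KO. Bmp2, a secreted BMP ligand, was listed at 0 in KO and had 9.25 in WT. The 2 cytokine genes Cxcl1 and Csf2, which act on neutrophils and myeloid cells, lay under the floor.

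Of the 28 gene lists, 4 had a higher median H3K36me3 ratio than level-matched random lists and 0 a lower one. In the cell-cycle list 12 of 26 measured members were at least 1.5-fold higher in KO and 5 lower (median 0.42, percentile 98.1). Its members with the widest differences, Cdkn1b (the inhibitor p27), E2f1 and Cdk4, had 16.8, 11.3 and 11.3 in KO and were listed at 0 in WT. Among Hox genes, which pattern the body axis, 12 of 20 were higher and 7 lower (median 0.86, percentile 99.6), yet Hoxb1 and Hoxa13 had 51.3 and 38.3 in WT and were listed at 0 in KO. Developmental regulators that Polycomb binds in many cell types had 18 of 44 higher and 12 lower (median 0.28, percentile 98.0). Olfactory receptors, which are silent outside the nose, had 142 of 229 higher and 82 lower (median 2.05, percentile 100). These 229 are the receptors past the floor; over all 1117, mean H3K36me3 per kilobase was 4.31 in KO and 3.60 in WT. In genes of at least 20 kb, an alternative chosen after seeing the data, 597 of 7402 genes were at least 2-fold higher and 804 lower, the cell-cycle median was -0.18 (percentile 31.5) and that of the developmental regulators 0.16 (percentile 84.8). The Hox and olfactory lists then held 3 and 4 genes, too few for a percentile. Random lists were matched on signal and not on gene span. H3K36me3 ratios spread far more in short genes (SD 3.23 under 3 kb, 0.44 at 100 kb and above). The percentiles at the main settings may thus overstate how far lists of short genes, such as Hox genes, stood apart.

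Long genes gave a steadier measure of the mark. The SD over genes of the log2 ratio was 3.23 in genes under 3 kb, where 70.8% of genes were listed at 0 in KO and 77.8% in WT, and 0.44 in genes of at least 100 kb. Among the 9310 genes of at least 20 kb, mean H3K36me3 was close in both genotypes where promoter H3K27ac was lowest (3.05 in KO, 3.11 in WT, log2 ratio -0.03 over the 882 long genes in the lowest of 5 groups, drawn over all genes by promoter H3K27ac) and lower in KO where promoter H3K27ac was highest (5.39 against 6.03, log2 ratio -0.16 over 2235 long genes in the highest group). The log2 contrast between those groups was 0.82 in KO and 0.95 in WT, a difference of -0.13, with an interval of -0.24 to -0.02 from resampling genes, which covers the spread over genes and not that between cultures.

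**Figure D1:**
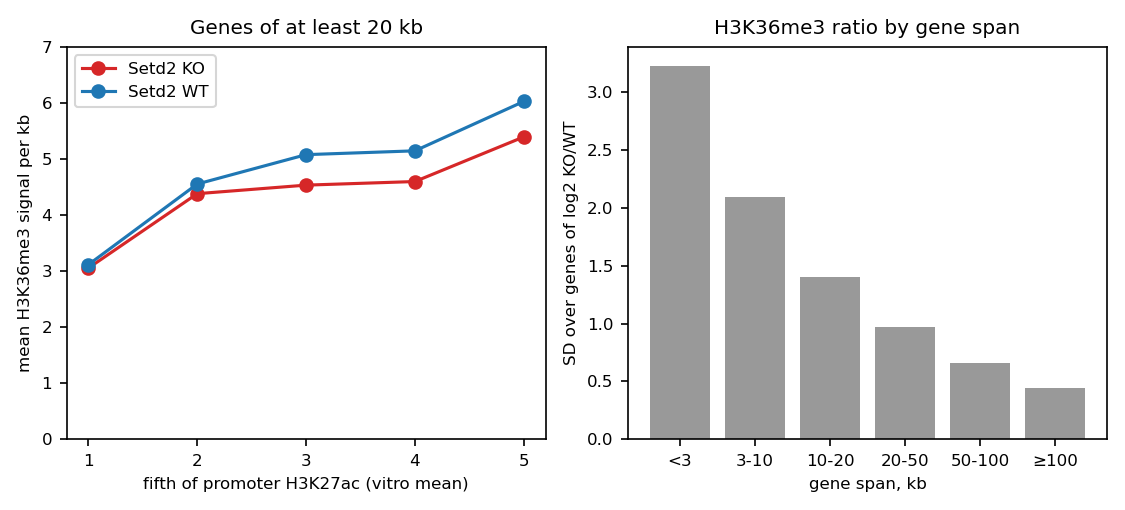
Left, mean H3K36me3 signal per kilobase in KO (red) and WT (blue) over genes of at least 20 kb, in 5 groups by mean vitro promoter H3K27ac (1 is lowest): the lines start at 3.05 and 3.11 and end at 5.39 and 6.03. Right, bars give the SD over genes of the H3K36me3 log2 ratio by gene span, from 3.23 under 3 kb to 0.44 at 100 kb and above.

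At the main settings, promoter H3K27ac without the vitro label was higher in KO at interferon, mesenchymal and fibroblast genes and lower at genes of pancreatic acinar cells. The mesenchymal list did not stand apart with the level trend removed, nor the fibroblast list with centring. Among named genes with a mean signal above the median, the highest ratios were at Iars2 (a mitochondrial tRNA synthetase, 59.1 in KO and 7.87 in WT, log2 ratio 2.48), Crocc2 (2.45), F2rl1 (the protease-activated receptor PAR2, 40.6 against 5.05), Prdm1 (the transcriptional repressor BLIMP1, 2.38), Fsd1 (2.29), Sorbs2os (2.28), Ccl2 (a monocyte chemoattractant, 29.2 against 3.44, log2 ratio 2.27) and Nsa2 (2.25, a window shared with Gfm2). The lowest of these were at Pdia2 (a protein disulfide isomerase of the pancreas, 7.56 in KO and 32.3 in WT, log2 ratio -1.72), Kif26a (-1.55), Paqr5 (-1.46), Cela2a (a pancreatic elastase, -1.42), Glmn and Rpap2 (-1.41 each, a shared window), Man1a (a Golgi mannosidase, -1.36) and Msmp (-1.31). Bmp2 had 22.1 in KO and 12.4 in WT (0.69, and 0.28 with quantile normalization or 0.25 with the level trend removed), Cxcl1 14.5 and 11.3 (0.29) and Csf2 7.01 and 9.76 (-0.34).

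In the same pair, 26 of 39 interferon-stimulated genes were at least 1.5-fold higher in KO and 3 lower (median 0.96, percentile 100), including the guanylate-binding proteins Gbp7 (1.87) and Gbp5 (1.82) and the poly-ADP-ribosyl transferase Parp14 (1.63). Of 23 mesenchymal genes 13 were higher and 0 lower (median 0.75, percentile 99.5), with fibronectin (Fn1, 1.55), the collagen crosslinker Lox (1.44) and the integrin Itga5 (1.28). Fibroblast markers had 12 of 21 higher and 2 lower (median 0.66, percentile 97.7), with the hyaluronan synthase Has1 (1.91), the collagen Col5a1 (1.58) and Pi16 (1.34). Of 24 acinar genes 0 were higher and 15 lower (median -0.69, percentile 0.00), with the digestive enzyme Cpa1 (1.64 in KO and 14.3 in WT, log2 ratio -1.84), the transcription factor Gata4 (-1.77) and the zymogen granule protein Zg16 (-1.73). In WT 18 of 23 acinar genes were higher than in vitro (median 0.95, percentile 100 of level-matched lists), a contrast that uses the same WT library, while the KO libraries of the 2 settings lay at percentile 70.8. Random genes matched on the KO over WT ratio as well, a check chosen after seeing the data, gave a median of 0.46 in WT (middle 95% 0.07 to 0.75), and the acinar list lay above such genes in WT (percentile 99.9) and in KO (percentile 99.6). Immune markers (median 0.02, percentile 43.9) and endothelial markers (0.04, percentile 20.9) did not stand apart between the genotypes.

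The whole distribution of this pair was shifted towards KO, with a median log2 ratio of 0.32 over 18673 genes, 2440 genes at least 2-fold higher and 807 at least 2-fold lower, and 3 further lists lay low relative to that shift. Epithelial and ductal genes had 5 of 37 higher and 6 lower (median 0.20, percentile 0.50), from the surface protein Prom1 (-1.53) and the nuclear receptor Hnf4g (-1.18) to the keratin Krt8 (1.08, and 0.35 with quantile normalization or 0.24 with the level trend removed). Oxidative phosphorylation subunits had 25 of 91 higher and 7 lower (median 0.23, percentile 1.31), including Cox6b2 (-1.51) and Ndufb6 (1.44). Splicing factors and readers of H3K36me3 had 8 of 27 higher and 0 lower (median 0.30, percentile 1.01), including the reader Psip1 (1.29) and the splicing factor Sf3b1 (1.03). Centred on the median of all genes, these 3 medians turned to -0.12, -0.08 and -0.02. With quantile normalization the epithelial and acinar lists still stood lower, while the oxidative phosphorylation list (percentile 3.60) and the splicing list (percentile 4.37) did not. The oxidative phosphorylation list also did not with the larger pseudocount or with the higher floor (percentile 3.81). Olfactory receptors had 32 of 101 higher and 23 lower (median 0.01, percentile 98.5), with a centred median of -0.31. Those 101 are the receptors past the floor; over all 1117 receptors mean H3K27ac was lower in KO (1.22 against 1.87, log2 ratio of means -0.61). The receptors did not stand apart with quantile normalization (percentile 57.1) or with the level trend removed (percentile 95.5), and 3 of them passed the higher floor, too few for a percentile. The ratio was higher at promoters with more signal: quantile normalization gave 1245 higher and 1153 lower, centring 826 and 1737, and removal of the trend with level, chosen after seeing the data, 848 and 844. With the trend removed the mesenchymal list lay at percentile 97.1, inside the range of random lists, and with centring the fibroblast list fell just inside it (median 0.34).

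**Figure D2:**
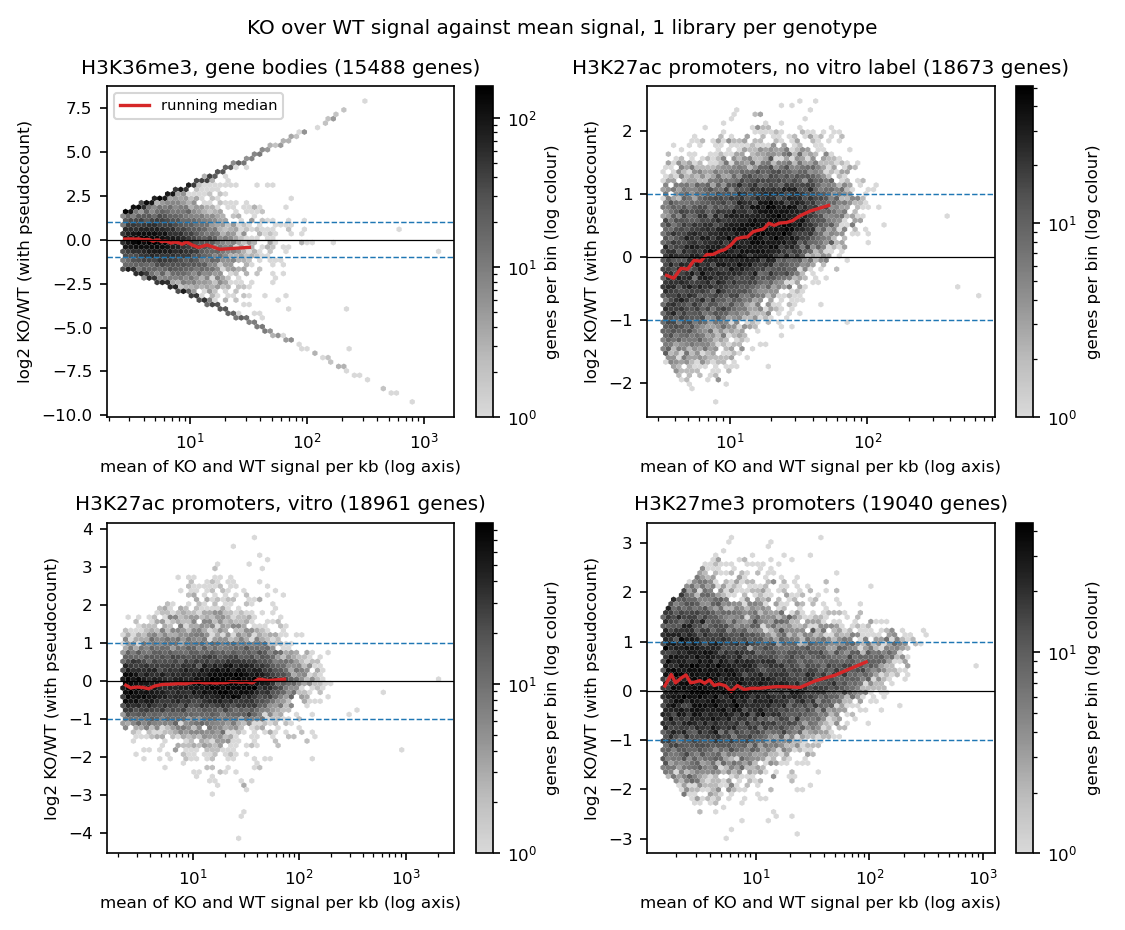
Log2 ratio of KO over WT against the mean signal per kilobase of the 2 libraries (log axis), in 4 panels; grey hexagons hold genes, the red line is the running median and dashed lines mark 2-fold. The red line climbs with signal in H3K27ac without the vitro label and stays near 0 in the vitro pair, and the diagonal edges in H3K36me3 are genes listed at 0 in 1 library.

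In the vitro pair, KO promoters carried more H3K27ac at fibroblast, mesenchymal and TGF-beta genes and less at genes of lipid and cholesterol synthesis. The lowest named ratio was at Gata4, an endodermal transcription factor (chromosome 14, 63198922 to 63271692, mm10), with a signal per kilobase of 1.03 in KO and 54.8 in WT (log2 ratio -4.15). The related factor Gata5 had 2.92 and 56.4 (-3.52) and its antisense neighbour Gata5os, whose window overlaps, -3.46. Tmem125 (-3.04), Pclo (a presynaptic scaffold, -2.90), the cadherin Cdh13 (-2.76) and the overlapping promoters of Fam187b and the lipoprotein receptor Lsr (-2.74 and -2.72) followed. The highest were Ptgs2os2 (46.7 in KO and 2.07 in WT, log2 ratio 3.52), the intestinal homeobox factor Isx (3.32), the cytokine receptor Crlf2 (3.13), Bach2os (3.05), the Polycomb subunit Phc2 (3.03), the fibrillar collagen Col5a1 (63.7 against 5.98, 3.01), the RNA-binding protein Igf2bp1 (2.97) and the matricellular protein Ccn4 (2.94).

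By list in the vitro pair, fibroblast markers had 10 of 17 members at least 1.5-fold higher and 1 lower (median 1.18, percentile 100), with Col3a1 (2.68) and Has1 (2.16). Mesenchymal genes had 10 of 21 higher and 1 lower (median 0.52, percentile 100), led by the transcription factors Twist2 (2.58), Twist1 (2.15) and Zeb2 (1.82). TGF-beta signalling had 9 of 21 higher and 1 lower (median 0.41, percentile 99.9), with Tgfbi (2.26), thrombospondin 1 (Thbs1, 2.15) and the activin subunit Inhba (1.24). Interferon-stimulated genes had 12 of 39 higher and 1 lower (median 0.28, percentile 99.98), with Parp14 (1.36), Gbp4 (1.34) and Mx2 (1.32). Glycolysis genes had 6 of 25 higher and 1 lower (median 0.33, percentile 99.9), with Pfkfb4 (1.09) and the glucose transporter Slc2a3 (0.83). Chemokines and neutrophil-acting cytokines had 5 of 31 higher and 0 lower (median 0.13, percentile 97.8), with Il6 (1.47), Ccl2 (1.18) and Il18 (1.13). The 2 fixed cytokine genes Cxcl1 and Csf2 had 41.3 against 37.9 (0.12) and 34.8 against 25.5 (0.42), and Bmp2 18.3 against 15.7 (0.19). Lipid and cholesterol synthesis had 2 of 31 higher and 12 lower (median -0.42, percentile 0.00), with the sterol demethylase Cyp51 (46.7 against 206, -2.09), the farnesyl diphosphate synthase Fdps (-1.44) and the desaturase Scd1 (-1.11). Over all 18961 genes the median was -0.07, with 749 genes at least 2-fold higher and 679 lower. The chemokine list lay inside the range of random lists with a 5 times larger pseudocount (percentile 97.0), and the split between higher and lower genes was 235 and 140 with that pseudocount and 875 and 534 with the level trend removed.

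**Figure D3:**
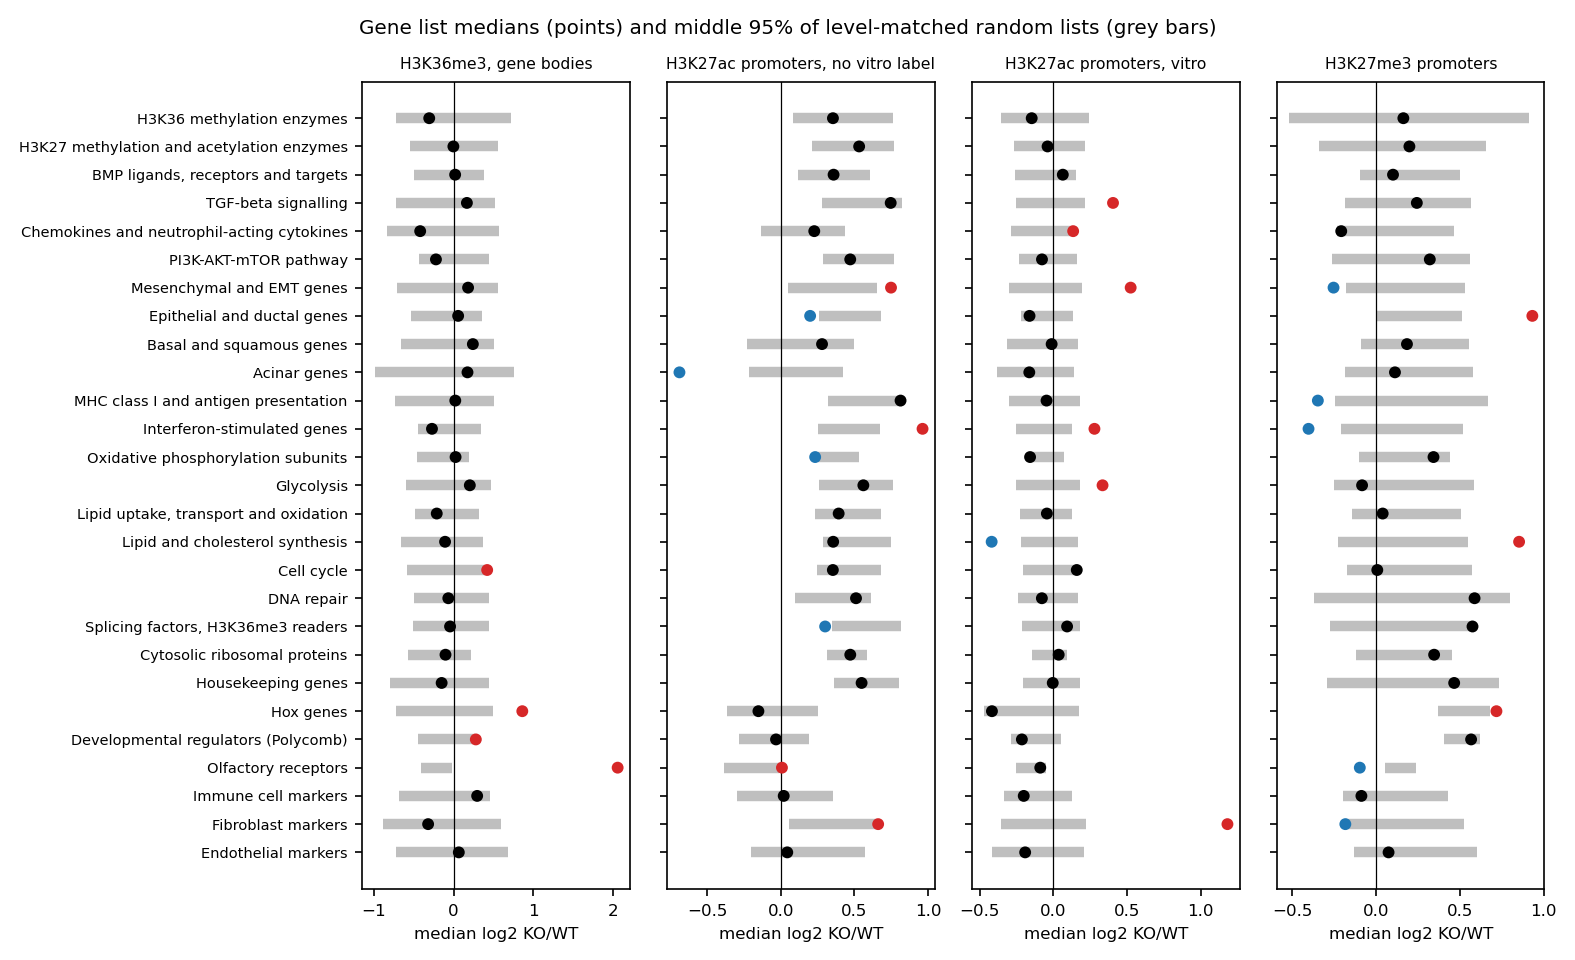
Median log2 ratio of KO over WT for gene lists (points) in the 4 comparisons, with grey bars for the middle 95% of level-matched random lists; red and blue points lie above and below that range. Acinar genes lie at -0.69 in H3K27ac without the vitro label, fibroblast markers at 1.18 in the vitro pair and epithelial genes at 0.93 in H3K27me3.

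Promoter H3K27me3 was higher in KO at epithelial, lipid synthesis and Hox genes and lower at interferon and antigen presentation genes. The highest named ratios were at the adaptor Grb7 (68.5 in KO and 6.80 in WT, log2 ratio 3.07), Lrba (3.03), the ubiquitin ligase Marchf9 (2.90), Tanc2 (2.78), the RAS effector Rassf5 (2.76), Plcb4 (2.72) and the RNA-editing enzyme Adar (2.70); Sord had 11.8 in KO and was listed at 0 in WT. The lowest were at Nlrc5, the transactivator of MHC class I genes (chromosome 8, 94434356 to 94527272, mm10; 0.44 in KO and 11.9 in WT, log2 ratio -2.77), Fstl5 (-2.23), Adgrg7 (-2.08), the metalloreductase Steap2 (-2.03), the acetyl-CoA carboxylase Acacb (-2.02) and the guidance factor Sema3a (2.03 against 12.7). Speer4e (-2.19) and Speer4c (-2.04) belong to a family of near-identical copies whose reads could be split between members. Bmp2 had 27.2 in KO and 31.5 in WT (-0.20), Csf2 5.88 and 7.84 (-0.34), and Cxcl1 lay under the floor.

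By list, 25 of 36 epithelial and ductal genes were at least 1.5-fold higher in H3K27me3 and 1 lower (median 0.93, percentile 100), with the tight junction genes Tjp1 (2.39) and Cldn3 (1.70) and the keratin Krt7 (53.7 against 13.9, 1.84). Lipid and cholesterol synthesis genes had 17 of 28 higher and 4 lower (median 0.85, percentile 99.9), with the cholesterol acyltransferase Soat1 (1.82), while Elovl1 was listed at 0 in KO with 5.92 in WT. Hox genes had 34 of 39 higher and 0 lower (median 0.72, percentile 99.5), with Hoxc8 (212 against 81.3, 1.37), Hoxc10 (1.19) and Hoxd8 (1.14). Level-matched random lists already had a median of 0.52, and neighbouring Hox genes such as Hoxc8 and Hoxc10 are not independent members. Developmental regulators that Polycomb binds had 38 of 80 higher and 1 lower (median 0.57, percentile 84.9) and did not stand apart. Interferon-stimulated genes had 5 of 32 higher and 15 lower (median -0.40, percentile 0.20), with Parp14 (-1.96) and Gbp5 (-1.75) against Trim25 (1.74). The MHC class I list had 3 of 18 higher and 8 lower (median -0.35, percentile 0.85), with Tap1, a subunit of the peptide transporter (-1.56), against Tapbpl (1.57). Mesenchymal genes had 4 of 23 higher and 7 lower (median -0.25, percentile 0.81), with Snai1 (-1.64) and Zeb2 (-1.34) against Itga5 (2.15). Fibroblast markers had 4 of 22 higher and 6 lower (median -0.18, percentile 2.48), with Col6a1 (-1.47), Lum (-1.39) and Col1a1 (-1.37). Olfactory receptors had 99 of 501 higher and 138 lower (median -0.10, percentile 0.00). Over 19040 genes the median was 0.18, with 2934 at least 2-fold higher and 1316 lower; with centring these were 2041 and 1954, with quantile normalization 2046 and 1908, and with the level trend removed 2102 and 1847. The fibroblast list lay inside the range of random lists under quantile normalization (percentile 2.82) and with the trend removed (percentile 3.77), and the lipid synthesis list with a higher floor, on 11 genes (percentile 97.3).

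Across the 17301 genes past the floor in both H3K27ac pairs, which share no library, the log2 ratios had a Spearman correlation of 0.21 and a Pearson correlation of 0.21 across genes, which are not independent replicates. At least 2-fold higher in both were 212 genes, against 89.7 for independent lists of those sizes, and 48 were lower in both, against 22.6. The genes higher in both by the widest margin were the BMP antagonist Grem1 (log2 ratios 2.04 without the vitro label and 2.16 in the vitro pair), Rab7b (2.03 and 2.59), Mab21l4 (80.0 against 17.5 and 90.7 against 21.3), Ccn4 (1.93 and 2.94), Ly6c1 (1.92 and 2.48), Has1 (1.91 and 2.16), Crocc2 (2.45 and 1.78) and the junction protein Jam2 (1.86 and 1.78). The genes lower in both included Fads6 (-1.19 and -1.66), Sh3tc1 (-1.13 and -1.26), Rundc3b (-0.99 and -2.05), Slc35c2 (-0.99 and -0.94), Proser2 (-0.91 and -0.95) and the transcription factor Mecom (-0.87 and -1.75). Dux (-1.24 and -1.40) lies in a tandem repeat, so its reads could come from several copies.

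**Figure D4:**
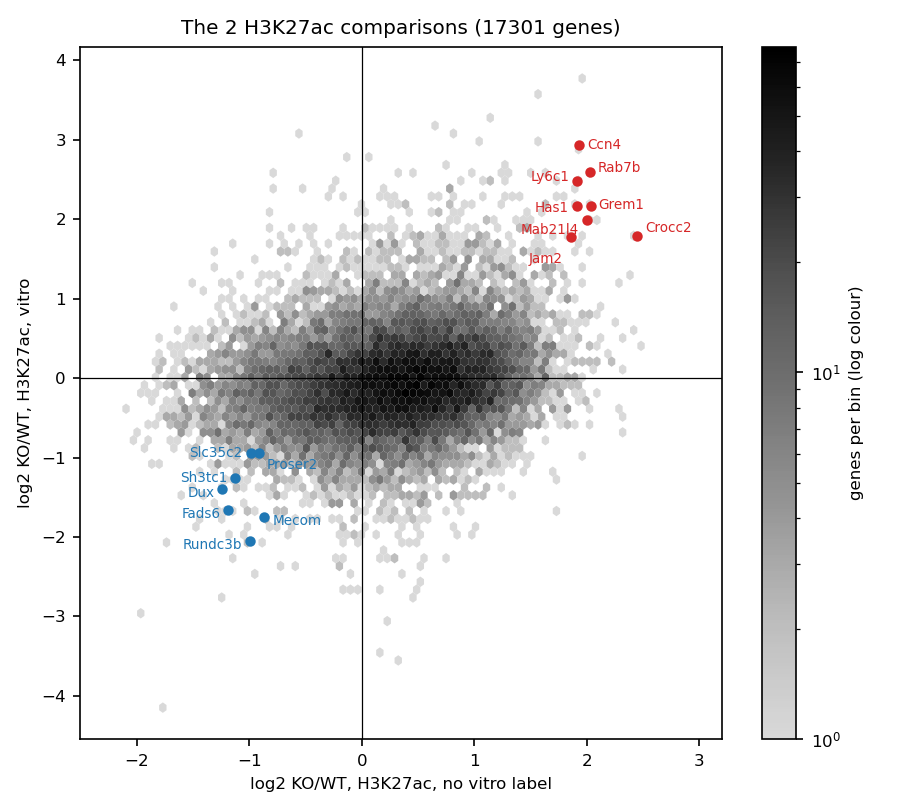
Log2 ratio of KO over WT in promoter H3K27ac for 17301 genes, without the vitro label (x axis) and in the vitro pair (y axis); grey hexagons hold genes, and red and blue points are the genes named as higher and lower in both pairs. The cloud tilts upward only slightly, with a Spearman correlation of 0.21 across genes.

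Set against H3K27me3, of the 8 genes ranked lowest in both H3K27ac pairs 5 were at least 1.5-fold higher in the repressive mark in KO and 0 lower, among them Fads6 (40.8 against 7.24, log2 ratio 2.27) and Mecom (81.0 against 22.2, 1.80), while Sh3tc1 (-0.21), Rundc3b (-0.24) and Dux (0.05) differed little. Higher ratios of that size were common: over all 19040 genes the upper quartile was 0.71, above the 1.5-fold size of 0.58, and the median 0.18. Slc35c2 (0.67) and Proser2 (0.73) lay close to that quartile. Of the 7 measured genes higher in both pairs, Rab7b was higher (1.34), Crocc2 lower (-0.94) and 5 differed by less, including Grem1 (0.07), Ccn4 (0.47) and Has1 (0.25). The H3K27me3 and H3K36me3 libraries carry no vitro label, so setting them against the vitro H3K27ac pair crosses the labels. In the vitro H3K27ac pair, 129 genes were at least 2-fold lower in H3K27ac and higher in H3K27me3, against 93.3 for independent lists, and 66 were higher in H3K27ac and lower in H3K27me3, against 35.0. The same counts in the pair without the vitro label were 59 against 108 and 130 against 107. By list in the pair without the vitro label, 8 of 30 interferon-stimulated genes and 7 of 18 genes of the MHC class I list were at least 1.5-fold higher in H3K27ac and lower in H3K27me3, with Tap1 and Psmb9 in nearly the same window, and 5 of 33 epithelial genes showed the opposite on both marks. Neither pattern was particular to these lists. Fibroblast markers showed the first in 4 of 17, and Hox genes (3 of 9), developmental regulators (5 of 34) and acinar genes (2 of 17) the second. The share over all genes at 1.5-fold was not measured. Over all genes the Spearman correlation of H3K27ac and H3K27me3 ratios was 0.021 without the vitro label and -0.057 in the vitro pair, and H3K36me3 ratios had correlations of 0.010, 0.019 and 0.0061 with H3K27ac in the 2 pairs and with H3K27me3. Genes of at least 20 kb with a WT H3K36me3 signal above 0 were put in 5 groups of 1785 by that signal. The median H3K27ac ratio in the vitro pair was 0.0051 in the lowest group and -0.09 in the highest. Without the vitro label it was 0.37 and 0.39 in those groups, but 0.08 and 0 with quantile normalization and 0.09 and -0.0069 with the level trend removed. For H3K27me3 it was 0.22 and 0.24, with 0.04 and 0.06 after quantile normalization and 0.06 and 0.05 with the level trend removed. The correlation of 0.021 changed sign with the setting, from 0.066 without a filter to -0.052 with the level trend removed.

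Between the settings, H3K27ac in both genotypes was higher in vitro at ribosomal protein genes and lower at antigen presentation, interferon, Hox and fibroblast genes. Ribosomal protein genes had 26 of 82 members higher and 2 lower in KO (median 0.37, percentile 100) and 51 of 84 higher and 3 lower in WT (0.73, percentile 99.7). The MHC class I list had 0 higher and 16 lower of 23 in KO (-0.89, percentile 0.00) and 3 higher and 7 lower in WT (-0.24, percentile 0.00), and interferon-stimulated genes 24 lower of 39 in KO (-0.77) and 15 lower in WT (-0.35). Hox genes had 21 of 24 lower in KO (-1.14) and 23 of 30 in WT (-0.73), and fibroblast markers 13 of 22 lower in KO (-0.72) and 14 of 18 in WT (-0.91). Olfactory receptors past the floor were lower too (-0.57 in KO and -0.56 in WT). Over all 1117 receptors, mean H3K27ac in KO was close in the settings (1.16 in vitro, 1.22 without the label). In WT it was 1.19 in vitro and 1.87 without the label. In WT, 18 of 23 acinar genes (-0.95, percentile 0.00) and 10 of 14 endothelial markers (-0.74, percentile 0.11) were lower in vitro. The KO medians of these lists were -0.33 (percentile 29.7) and -0.63 (percentile 3.73), and the difference between genotypes was not tested. In KO the cell-cycle list (0.32, percentile 99.7) was higher in vitro.

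Of 17661 genes, 447 were at least 2-fold higher in vitro in both genotypes and 344 lower. The tetraspanin Cd53 (log2 ratio of vitro over the other setting 2.36 in KO and 2.63 in WT), the aldehyde dehydrogenase Aldh3a1 (2.09 and 2.09) and the clustered histone genes H2ac15 (2.57 and 2.13), H2bc15 (2.56 and 2.11) and H3c6 (2.76 and 2.08), which share signal between close copies and neighbours, were the highest. The growth factor Clec11a (-2.75 and -2.05), the cytokine-signalling inhibitor Cish (-2.18 and -1.90), Sorbs3 (-1.87 and -2.53), the sphingosine phosphate transporter Spns2 (-2.22 and -1.75) and the protease Tmprss4 (-2.87 and -1.45) were the lowest. The all-gene median was -0.08 in KO and 0.28 in WT, and quantile normalization gave 295 higher and 305 lower in both.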

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

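Tests of acinar signal in the wild-type library and of read number per gene body were set before their results were seen; the other tests in this part were chosen after. The 5 groups by promoter H3K27ac were first drawn from the WT vitro library alone and then regrouped so that no pair was ranked by itself; the first grouping gave contrast differences of 1.27, -0.05 and -0.18 where the values below are 1.31, 0.02 and -0.13.

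The 2 H3K27ac pairs lay in opposite directions at the median gene, 0.318 without the vitro label and -0.0672 in the vitro pair, a difference that was not tested and that quantile normalization removed (-0.0088 and -0.02). Without the vitro label, the KO library had more signal at strong promoters and less at silent ones, with log2 ratios of mean signal of 0.69 in the top group and -0.61 (-0.614) at olfactory receptors. The difference between these, 1.31, with an interval of 1.17 to 1.44 from resampling genes, argues against 1 scaling factor between the libraries, which would move both alike. The same contrast was 0.02 (0.0210) in the vitro pair. With 1 library per group, a different share of background could make or mask such a contrast in either pair. The values therefore do not decide whether the genotype effect differed between the settings. A lower share of background reads in the KO library and a true rise of H3K27ac at active promoters both predict the drop at silent promoters after scaling, so they cannot be told apart without read counts or a second library.

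Acinar promoters were low in H3K27ac in the KO library without the vitro label. Removing the level trend left the list's median at -0.74, which argues against the trend as the whole cause, and its H3K27me3 ratio lay at percentile 33.2 of random lists, which argues against a general gain of that mark, although Gata4 had more of it (170 against 37.1). In WT, the list was higher without the vitro label than in vitro at percentile 100 (median 0.95), with Cpa1 at 14.3 against 4.25, Zg16 at 17.1 against 2.70 and Pnlip at 11.9 against 3.33, but fibroblast (-0.91), endothelial (-0.74) and Hox (-0.73) medians were also lower in vitro beyond matched lists in WT, so that shift is not particular to acinar genes. That contrast and the genotype contrast share the WT library, and genes matched on the genotype ratio gave 0.46 in WT by that alone. The acinar list lay above such genes at percentile 99.9 in WT and 99.6 in KO. In KO this matching picks genes low in the KO library without the vitro label, with a median of -0.16. Against lists matched on level alone, the KO list lay at percentile 70.8. Whether the excess is particular to WT thus depends on the matching and is not settled. Signal from acinar cells carried into the WT library is thus 1 open candidate, though Rnase1 was about as high in KO (14.2 against 14.6), Cela1 and Prss2 were not lower there, and the cell sorting that the series title names should remove such cells; an acinar programme within WT tumour cells remains open and untested.

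H3K36me3 was at most slightly lower in the KO library, with a median log2 ratio of -0.08. Mean signal per kilobase over all genes was 5.20 in KO and 5.80 in WT, while the median was 3.01 and 2.73. In genes of at least 20 kb, 597 were at least 2-fold higher and 804 lower. The SD of the log2 ratio in genes of at least 100 kb was 0.315 of that in genes of 10 to 20 kb, as too few reads per gene body would give, so ratios of short genes may be counting noise. Per-library scaling could hide a uniform loss of the mark, and a proportional loss would leave the contrast between genes with much and little promoter H3K27ac unchanged unless a background signal remained, which was not measured. That contrast differed by -0.13 (-0.132, interval over genes -0.24 to -0.02) and so sets no limit on such a loss. A larger loss hidden by scaling, the small difference printed here and no loss cannot be told apart.

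Of 190 named genes measured in both H3K27ac pairs, 6 differed by at least 1.5-fold in opposite directions, and none of these differences was tested. They rest partly on the shift of the whole library without the vitro label: 2 of the 6 kept opposite directions of that size with centring (Hoxb13 and Rps9), the same 2 with quantile normalization, and 1 (Rps9) with the level trend removed. The immediate-early factor Egr1 had log2 ratios of 0.70 (0.705) without the vitro label and -0.71 (-0.705) in the vitro pair. The sterol synthesis gene Hmgcs1 had 0.95 and -0.65. The desaturase Scd1 had 0.85 and -1.11. The peptide transporter subunit Tap2 had 0.75 and -1.03. Hoxb13 had -0.81 and 0.62. The ribosomal protein gene Rps9 had -0.65 and 0.96.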

How the results depend on the processing

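The level-trend removal and the restriction to genes of at least 20 kb were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each group has 1 library, and for the same reason leaving out a library was not possible. The cause of each move below was not tested unless the alternative itself fixes it: centring and trend removal set a median to 0, larger pseudocounts shrink ratios, and stricter filters test fewer genes.

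For H3K36me3, the median of -0.08 was -0.11 with a pseudocount 5 times smaller, -0.03 (-0.032) with 5 times it, 0 without a filter, -0.16 with the higher floor, -0.03 (-0.030) after quantile normalization and 0 with centring or trend removal. Genes higher and lower were 934 and 1025 with the larger pseudocount, 2038 and 2403 with the higher floor, and 597 and 804 in long genes. For H3K27ac without the vitro label, the median of 0.32 was 0.39, 0.17, 0.12, 0.47, 0 and 0 with the smaller and larger pseudocounts, no filter, the higher floor, centring and trend removal, and turned to -0.0088 after quantile normalization. Higher genes were 298 with the larger pseudocount, 826 with centring, 1245 with quantile normalization and 848 with trend removal. Lower genes were 1645 and 1 with the smaller and larger pseudocounts, 1287 without a filter, 143 with the higher floor and 1737 with centring. In the vitro pair the median of -0.07 was -0.08 (-0.079) and -0.04 (-0.038) with the smaller and larger pseudocounts, -0.03 (-0.030) with the higher floor, -0.02 (-0.023) with quantile normalization and 0 with centring or trend removal. Lower genes were 1355 with the smaller pseudocount, and 235 were higher and 140 lower with the larger. For H3K27me3 the median of 0.18 was 0.21, 0.10 (0.096), 0.14, 0.16, 0 and 0 with the smaller and larger pseudocounts, no filter, the higher floor, centring and trend removal, and turned to -0.01 (-0.015) after quantile normalization. Lower genes were 2180 with the smaller pseudocount, with 420 higher and 73 lower for the larger and 1473 and 700 for the higher floor.

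Genes higher and lower in both H3K27ac pairs were 359 and 185 with the smaller pseudocount, 29 and 0 with the larger, and 124 and 79 with centring; 118 were higher in both with trend removal and 15 lower in both with the higher floor. Their Spearman correlation was 0.19 (0.186) with the larger pseudocount, 0.16 without a filter, 0.23 with the higher floor and 0.19 (0.193) with quantile normalization. The correlation of H3K36me3 and H3K27ac without the vitro label turned to -0.012 without a filter. That of H3K27ac without the vitro label and H3K27me3 was 0.066 without a filter and turned to -0.0034, -0.035 and -0.052 with the larger pseudocount, quantile normalization and trend removal; in the vitro pair it was -0.032 without a filter and -0.073 with the larger pseudocount. Genes higher in vitro in both genotypes were 110 with the larger pseudocount, with 5 lower, and 295 with quantile normalization. Lists standing higher numbered 1 for H3K36me3 in long genes, a list outside the 4 that stood higher at the main settings. They numbered 2 for H3K27ac without the vitro label with trend removal, where the mesenchymal and olfactory lists lost the call, and 5 for H3K27me3 with the larger pseudocount. Lists standing lower with quantile normalization were 2 in each H3K27ac pair, against 4 without the vitro label and 1 in the vitro pair at the main settings. The oxidative phosphorylation and splicing lists lost the call without the vitro label, and the oxidative phosphorylation list gained it in the vitro pair (percentile 2.18).

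Of the named genes with a ratio, 16 fell under the 1.5-fold size with the larger pseudocount, 6 with trend removal, 4 with quantile normalization and 3 with centring, and none turned direction past that size. Krt8 without the vitro label was 0.35 and 0.24 with quantile normalization and trend removal, and Bmp2 0.28 and 0.25. What limits these data is the single library per group and the unknown depth, most of all for short genes in H3K36me3.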

Other observations

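The genes and list relations in this part were chosen after their values were seen, and no test was run on them. Single transcription factor genes of pancreatic and foregut endoderm, for which no list was set, differed in direction. Gata4 and Gata5, lowest of the named genes in the vitro pair, had H3K27me3 log2 ratios of 2.15 and 1.49. Gata6 had H3K27ac ratios of -0.85 without the vitro label and -0.86 in the vitro pair, with an H3K27me3 ratio of 1.06. Onecut1 had -0.64, -0.74 and 1.40 in the same order. Hnf4a had -0.30, -1.59 and 0.31, and the epithelial cadherin Cdh1 0.27, -1.73 and 0.87. In the other direction for H3K27ac, Sox9 had 0.96, 0.82 and 0.87, and Pdx1 0.35, 0.52 and 1.01. Gata5 itself had a ratio of 0.30 without the vitro label.

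The MHC class I and antigen presentation list stood apart in neither H3K27ac pair (percentile 96.9 without the vitro label and 55.6 in the vitro pair), and the difference between the pairs was not tested. At single genes without the vitro label, Tap1 and the immunoproteasome subunit Psmb9, whose promoter windows hold nearly the same values and count as 1 observation, had H3K27ac log2 ratios of 1.83 each and H3K27me3 ratios of -1.56 and -1.43, and Nlrc5 had 0.80 and -2.77. In the vitro pair the H3K27ac ratios of Tap1, Psmb9 and Nlrc5 were -0.10, -0.03 and -0.04. The class I gene H2-K1 had 0.52 without the vitro label and -1.36 in the vitro pair, and its near-identical relatives could share reads.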
